A study of Ovis aries with 2 samples.

How the data were processed

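Sheep peripheral blood mononuclear cells were isolated on a HISTOPAQUE density gradient and used without culture, per the labels' protocols. Libraries were made with the SeekOne DD kit, a droplet method that reads the 3′ end of transcripts and tags each molecule with a unique molecular identifier (UMI), and were sequenced on a GeneMind SURFSeq instrument. The labels give 1 library to each of 2 groups, untreated and A.G.-ES, and do not say how many animals gave blood for a library. For each library the authors deposited a matrix of raw UMI counts per gene and barcode, with its gene names and barcodes. The aligner, counter, genome build and cell caller are not given in the sources used here. No other column of per-sample values was left aside (0 columns).

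The counts carried 26814 gene names, of which 16433 were gene symbols and the others LOC numbers. A RefSeq gene table of the assembly ARS-UI_Ramb_v3.0 matched 26761 of the 26814 names and was used only to tell which genes lie on the Y chromosome, since the build behind the counts is not known. Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 15% of UMIs from mitochondrially encoded genes, which removed 158 untreated and 186 A.G.-ES barcodes. Doublets were scored with Scrublet in scanpy 1.11.5, and in each library the highest-scoring cells were taken out at 0.8% per 1000 cells, which came to 523 and 715 cells (6.47% and 7.56%). Scrublet's own threshold marked 221 and 197 cells (2.73% and 2.08%). The 7565 and 8737 cells left had a median of 5123 and 4101 UMIs.

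Cells of both libraries were clustered together, with no batch integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen per library, values were scaled with a maximum of 10, and 30 principal components and 15 neighbours entered Leiden clustering at resolution 1 (igraph 0.11.9, 5 iterations). Clusters were named from marker genes fixed before the data were examined. The rule that turns markers into names was chosen after the clusters were seen. Expression was taken as CPM, UMIs per 1000000. Each cluster was scored on the mean scaled expression of each class's markers, and of the classes within 0.15 of the best score it took the one with the most detected markers (at least 20 CPM and a scaled value of at least 0.5). A cycling score of at least 0.5 took precedence, and T-cell subsets needed a subset score of at least 0.4. A cluster whose top 10 genes by fold, with a pseudocount of 10 CPM, held at least 2 more markers of another class took that class. A cluster stayed unnamed with under 4 detected markers, with more markers of another class than of its own among those genes, or with a median depth under that of the library giving most of its cells, divided by 3. CD8 T and NK cells were taken as 1 class, scored on markers of both together, and their separation was not tested. Clusters 6, 8 and 15 of that class each carried CD8A and NCR1, but CD8B was detected in 6 and 8 and not in 15. Clusters with T-cell markers and high SOX13 and RHEX, 2 of the markers listed for gamma-delta T cells, were called SOX13-high T-like, because the receptor genes of that lineage were not analysed here. T-like clusters without markers of a subset were called other T-like. Of 27 clusters 4 stayed unnamed. They were cluster 1 (few UMIs per cell, 80 and 142 cells), cluster 4 (nearest to platelets, with 3 detected markers, 99 and 25 cells), cluster 19 (1 and 27 cells) and cluster 26 (0 and 46 cells).

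Raw counts were summed per library over all kept cells, over each class with at least 200 cells in both libraries and over all T-like cells, and expressed as CPM of that sum. A gene's ratio is A.G.-ES over untreated, with an exact conditional binomial interval on its counts. CPM carry exact Poisson intervals and shares of cells exact (Clopper-Pearson) binomial intervals, all at 95% and for counting error only. With 1 library per group no test between treatments was made. Where a gene had 0 UMIs in a library, a bound on the fold was taken against a floor of 3 counts summed over that library.

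Fixed before the data were examined were the groups, the filters, the clustering settings, the marker genes, the gene lists, the rule for named genes and most alternatives. Named genes had to have a gene symbol. They were the 10 highest and 10 lowest ratios of the whole library among genes with at least 200 UMIs over both libraries, the 5 highest and 5 lowest in each class among genes with at least 100, every Treg and Th17 list member with at least 20 UMIs in T-like cells, and for other lists 2 to 4 members with the most UMIs or the largest ratios. Some genes that this rule names are not reported here, and list medians and member counts still hold every measured member. The 29 gene lists covered Treg, Th17, Th1 and Th2 genes, naive and central memory T genes, cytotoxic effectors, immediate early genes, heat shock, interferon response, MHC class II, NF-kB and inflammatory cytokines, TGF-beta signalling, IL-2 and IL-6 JAK-STAT signalling, glucocorticoid response, antioxidants, nuclear oxidative phosphorylation, apoptosis and p53, inhibitory receptors, proliferation, phagocytosis and pattern recognition, antibody secretion, B-cell activation, homing and chemokine receptors, X-inactivation and Y-linked genes, markers of neutrophils, platelets and erythroid cells, ribosomal proteins and mitochondrially encoded genes. The ribosomal list took every name that starts with RPL or RPS and so also holds ribosomal S6 kinases such as RPS6KA5. Several genes stand in more than 1 list.

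A list's value is the median log2 CPM ratio of its members with at least 20 UMIs over both libraries, with its interval from 1000 Poisson resamples of the counts. Members at least 1.5-fold apart were counted as higher or lower. The median was placed among 10000 random lists of the same size, each gene replaced by one of its 200 nearest in mean expression, and called past the range below percentile 2.5 or above percentile 97.5. For shares of cells with a FOXP3 UMI, each cell was thinned to 1500 UMIs and shallower cells were left out. Where no cell had a UMI, the limit given is 3 counts divided by the number of cells, and not the exact interval.

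The calculations were tested on simulated counts drawn from the means and totals of these libraries, with 200 genes changed. For the whole library, the 95% intervals held the true ratio for 95.5% of 10611 genes, all 50 genes raised 2-fold, all 47 lowered 2-fold, all 50 raised 4-fold and all 46 lowered 4-fold came out in the right direction, and a list of 20 genes raised 2-fold had a median of 0.99 at percentile 100. An unchanged list had a median of −0.03 at percentile 15.3. For CD4 T-like cells the intervals held for 96.0% of 8236 genes. The simulated counts were Poisson draws, the model on which the intervals rest, so a coverage near 95% was fixed beforehand. They hold no spread between cells or animals, and the test covers the calculation alone.

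Alternatives were all deposited barcodes, a filter at 1000 UMIs, 500 genes and 10% mitochondrial UMIs, doublets kept or taken at Scrublet's own threshold, Leiden resolution 0.5 and 2, each library clustered on its own, 4000 variable genes with 50 components, TMM factors (edgeR 4.0.16 in R 4.3.3), CPM without ribosomal, mitochondrial and haemoglobin genes (92, 13 and 4 genes; immunoglobulin genes were in the plan, but the rule used for them took out 0 genes), ratios centred on the median gene, the mean of each cell's CPM (every cell given the same weight), cells thinned to 1500 UMIs before summing, no count minimum and a minimum 5 times higher, and thinning to 1000 or 2500 UMIs or none for shares of cells. Added after the data were seen were clustering on the marker genes alone, leaving Y-chromosome and mitochondrial genes out of the variable genes, and comparing monocyte-like cells although the untreated library held fewer than 200. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were also used.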

Results

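Peripheral blood mononuclear cells of sheep were profiled by droplet-based single-cell RNA sequencing in 2 libraries. The untreated library came from animals that received nothing, and the A.G.-ES library from animals with a suture embedded at ST36 on both sides. ST36 is an acupuncture point, and the series title describes the suture as releasing astragaloside IV, a saponin of Astragalus root, and glycyrrhizic acid, a saponin of liquorice root. The files held 8246 barcodes with 55861418 unique molecular identifiers (UMIs) for the untreated library and 9638 barcodes with 44485442 UMIs for the A.G.-ES library. The median barcode had 5200 UMIs and 1898 genes in the former and 4165 UMIs and 1514.5 genes in the latter. After filtering and doublet removal, 7565 untreated and 8737 A.G.-ES cells remained, with 50488226 and 39259466 UMIs.

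With 1 library per group, no difference has a replicate check and no test between the treatments was possible. All intervals are 95% intervals and cover counting error only. Percentiles of gene lists describe these libraries against 10000 random lists of like expression. Where a list's median moved by at least 1.5-fold under an alternative way of working, its range over the alternatives, or the alternatives that moved it, are given. The libraries also differed in genes of the Y chromosome. A set of 6 Y-linked genes, picked after their values were seen, gave 38751 UMIs in the untreated library, with at least 1 in 89.2% of cells (88.5 to 89.9%). The A.G.-ES library had 9 such UMIs, in 0.103% of cells (0.0471 to 0.195%), and all 85 Y-linked genes gave 40414 and 755 UMIs. This difference ran alongside the treatment in every comparison. SRY, the testis-determining gene and the single member analysed here of the list of X-inactivation and Y-linked genes, had 0 UMIs in both libraries. It was absent also from the untreated library, where other Y-linked genes were counted, so SRY decides nothing about sex here. Mitochondrially encoded genes took 1.37% of UMIs in the untreated and 2.20% in the A.G.-ES library.

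The first comparison asked how the blood cell classes were divided in each library. B-like cells, named from genes such as MS4A1, CD79B and PAX5, were 45.3% of untreated cells (44.2 to 46.4%) and 22.2% of A.G.-ES cells (21.4 to 23.1%). T-like cells together were 47.3% (46.2 to 48.4%) and 71.3% (70.4 to 72.3%). Within them, CD4 T-like cells were 11.1% (10.4 to 11.8%) and 35.4% (34.4 to 36.5%), and CD8 T/NK-like cells 5.68% (5.17 to 6.23%) and 21.0% (20.2 to 21.9%). T-like cells with high SOX13, a transcription factor gene, went the other way, at 30.5% (29.5 to 31.5%) and 12.99% (12.3 to 13.7%). Cycling cells were 2.64% (2.29 to 3.03%) and 0.378% (0.260 to 0.530%), and monocyte-like cells 2.37% (2.04 to 2.73%) and 3.32% (2.95 to 3.72%). Other T-like cells numbered 1 in the untreated and 162 in the A.G.-ES library, and clusters left unnamed held 2.38% and 2.75% of cells.

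Of the 27 clusters, 20 drew over 80% of their cells from 1 library, and such a cluster may be that library and not a cell type. B-like cells lay mostly in clusters 3, 13, 16 and 17 in the untreated library and in clusters 20, 21 and 22 in the A.G.-ES library. SOX13-high T-like cells lay mostly in clusters 2 and 14 against 9 and 12. CD4 T-like cells lay mostly in cluster 11 in the untreated library, with 541 of 841 cells, and in clusters 0 and 7 in the A.G.-ES library, with 1323 and 891 of 3097. CD8 T/NK-like cells were spread over clusters 6, 8 and 15 in both libraries. Values within a class can thus also mix its division into clusters with expression per cell. Median depths were 8567 and 5035 UMIs in untreated and A.G.-ES B-like cells, 4634 and 4182 in CD4 T-like, 3915 and 4087 in SOX13-high T-like and 3525 and 3142 in CD8 T/NK-like cells.

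**Figure D1:**
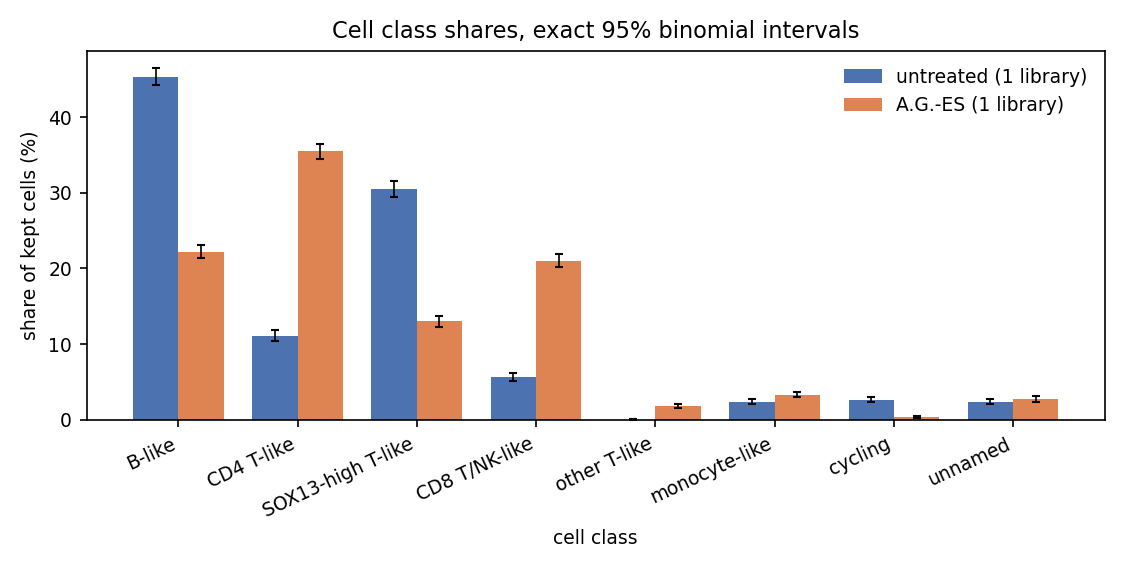
Share of kept cells (%, vertical axis) in each cell class (horizontal axis) in the untreated library and the A.G.-ES library, with exact 95% binomial intervals that cover counting error only. B-like cells were 45.3% against 22.2%, and CD4 T-like cells 11.1% against 35.4%.

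The series title names the balance of regulatory T cells (Treg) and IL-17-producing helper T cells (Th17), so genes of both were compared within T-like cells. In CD4 T-like cells, FOXP3, the transcription factor that defines Treg, was at 18.7 CPM (UMIs per 1000000; 14.7 to 23.4) in the untreated and 7.48 CPM (6.09 to 9.10) in the A.G.-ES library, from 76 and 100 UMIs. The log2 ratio was −1.32. Over all T-like cells, where CD4 T-like cells were a larger part of the A.G.-ES library, FOXP3 was at 5.79 and 4.79 CPM.

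Of 13 Treg list members measured in CD4 T-like cells, 3 were at least 1.5-fold higher and 6 at least 1.5-fold lower in the A.G.-ES library. The higher ones were IL10 (log2 ratio 1.28, from 5 and 40 UMIs), the chemokine receptor gene CCR8 (0.99) and the inhibitory receptor gene CTLA4 (0.89). The interval of IL10 (ratio 2.43, 0.960 to 7.89) includes no change. Beside FOXP3, the lower ones were TNFRSF18 (−1.63), IKZF4 (−1.43), IKZF2 (−1.38), TGFB1 (−1.07) and TNFRSF4 (−0.62). TIGIT (0.55), ICOS (0.23), IL2RA (0.07) and PRDM1 (−0.30) lay between. The list's median was −0.30, at percentile 21.0 of random lists, and ranged from −0.49 to −0.075 over the alternatives tried. The Th17 list had a median of −0.46, at percentile 0.845, and −0.27 with TMM scaling; of its 13 members measured, 1 was higher and 5 were lower. The higher one was IL23R, at 1 and 22 UMIs (6.69-fold, 1.08 to 276). The lower ones included IL17F (−1.72), RORA (−0.76), the receptor gene IL6R (−0.75) and CCR6 (−0.69), with AHR (−0.58), BATF (−0.46), IL6ST (−0.37), STAT3 (−0.35), IL1R1 (−0.27), IRF4 (−0.25) and MAF (0.19) between. IL17A and IL22, the genes of the main Th17 cytokines, had 0 UMIs in the CD4 T-like cells of both libraries.

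Over all T-like cells the Treg list's median was 0.21, at percentile 99.2, with 7 of 16 members higher and 2 lower, and 0.60 with cells thinned and 0.51 with a count minimum 5 times higher. The higher members included CTLA4 (2.69), CCR8 (1.94), TIGIT (1.28) and IL2RA (1.12), and the lower ones were EBI3 (−1.72) and TGFB1 (−0.74). CTLA4, CCR8, TIGIT, IL2RA, IKZF2, IKZF4, TNFRSF18, TNFRSF4, RTKN2, ICOS and FOXP3 of the Treg list and IL23R, IL1R1, CCR6 and IL17F of the Th17 list were also on the marker lists of the CD4 T-like class, which was larger in the A.G.-ES library. CTLA4 was also the leading gene of the other T-like cluster, with 1 and 162 cells, and CD4 T-like cells held 705 of the 1321 CTLA4 UMIs of A.G.-ES T-like cells. The Th17 median over all T-like cells was −0.08, at percentile 57.7, with 2 of 13 members higher, IL23R (3.42) and IL1R1 (1.12), and 2 lower, CCR6 (−0.82) and IL6ST (−0.73). With every cell given the same weight that median was 0.22, and with TMM 0.038 and cells thinned 0.073.

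**Figure D2:**
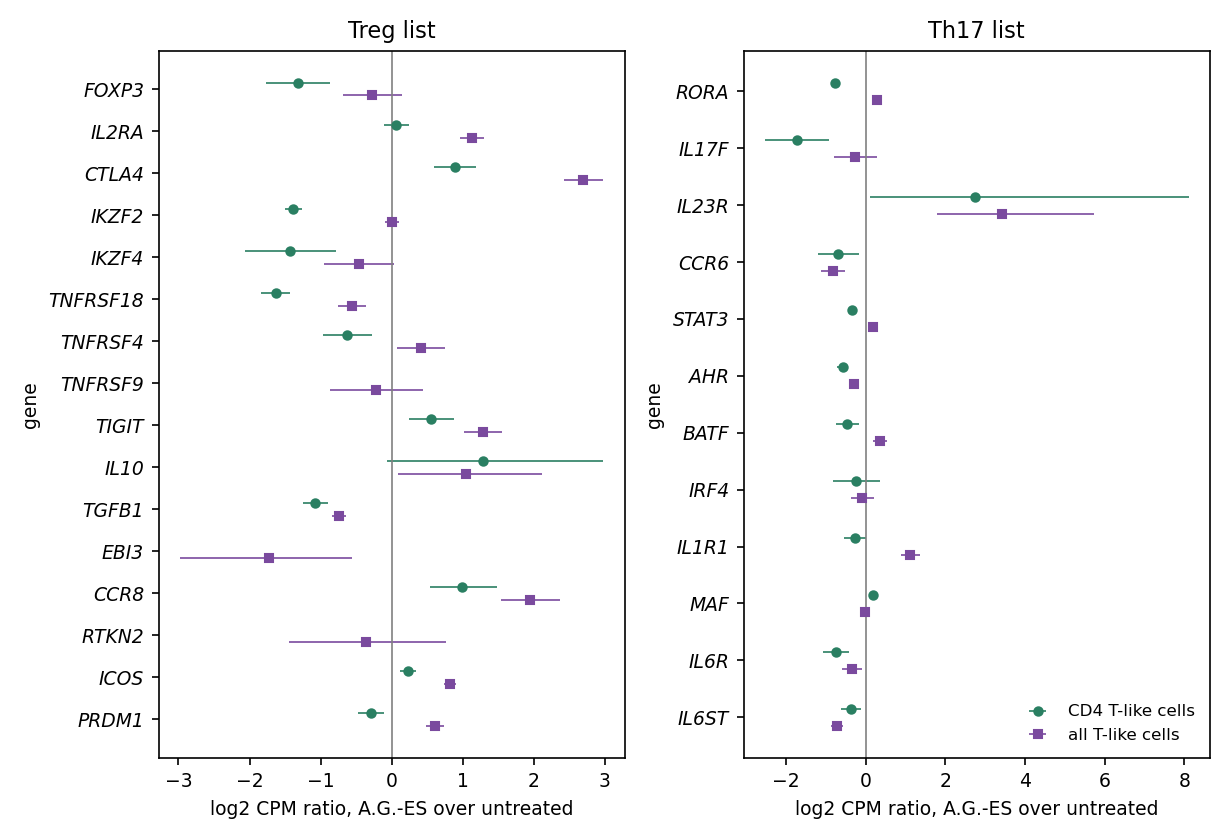
Log2 ratio of CPM in the A.G.-ES over the untreated library (horizontal axes) for genes of the Treg list (left) and the Th17 list (right), in CD4 T-like cells (circles) and in all T-like cells (squares). Bars are exact conditional 95% intervals of counting error; FOXP3 lies at −1.32 in CD4 T-like cells and at −0.27 in all T-like cells.

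Per cell, thinned to 1500 UMIs, a FOXP3 UMI was found in 3.44% of CD4 T-like cells of the untreated library (27 of 785, 2.28 to 4.97%) and in 1.12% in the A.G.-ES library (33 of 2946, 0.772 to 1.57%). Thinning left out 56 and 151 CD4 T-like cells with fewer UMIs. The difference in the FOXP3 share was −2.32 points, and −0.842 points when cells were thinned to 1000 UMIs. Without thinning the FOXP3 shares were 6.42% (4.86 to 8.30%) and 2.71% (2.17 to 3.35%). In B-like cells, which should lack the gene, the thinned share was 0.0930% and 0.161%. In monocyte-like cells FOXP3 was found in 0.621% of untreated cells (1 of 161) and in 0 of 275 A.G.-ES cells, which allows up to 1.09%. Over all T-like cells the thinned FOXP3 share was 0.897% (0.606 to 1.28%) and 0.688% (0.492 to 0.936%), with 234 and 421 cells left out.

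Within B-like cells, genes of cell division and of antibody secretion were lower in the A.G.-ES library, and interferon-stimulated genes were higher. Cluster 13, with JCHAIN and DERL3 among its leading genes, held 10.9% of untreated and 2.11% of A.G.-ES B-like cells. The values below do not separate such shifts between clusters from expression per cell. Of 19 proliferation genes, 13 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of −1.30 (percentile 0); RRM2, a subunit of ribonucleotide reductase, fell by 3.39, with 60 and 2 UMIs, and HMGB2 by 0.21. Its range was −1.40 to −0.39, the latter with cells thinned. Of 10 antibody secretion genes, 6 were lower and 0 higher (median −0.89, percentile 0.01, range −0.89 to −0.56), among them MZB1 (−2.28) and JCHAIN (−1.51), which joins polymeric antibodies, while SSR4 stood at −0.44. Of 30 interferon response genes, 17 were higher and 0 lower (median 0.74, percentile 100, range 0.42 to 0.87), led by HERC6 (2.41) and IRF7 (1.92), while MX1, the one with the most UMIs after EPSTI1 (0.26), was at −0.20. Nuclear genes of oxidative phosphorylation had a median of −0.42 (percentile 0.29; 5 of 26 lower), with SDHB at −0.91.

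Further lists were higher in B-like cells. Naive and central memory T genes had 8 of 15 members higher and 3 lower (median 0.63), with KLF7 at 1.32 and FOXO1 at −1.33. Glucocorticoid response genes had 6 of 14 higher (0.51), with TSC22D3 at 1.27 and KLF9 at 2.47. Homing receptors had 7 of 15 higher and 1 lower (0.43, range 0.37 to 0.66), with ITGB1 at 0.60 and GPR15 at 1.52. B-cell activation genes had 5 of 15 higher and 2 lower (0.21, range 0.10 to 0.35), with FCER2, the low-affinity IgE receptor gene, at 1.95, CD80 at 1.25 and MYC at −1.54. The IL-2 and IL-6 JAK-STAT list stood at 0.23 (range 0.19 to 0.36; 5 of 17 higher, 2 lower; JAK1 at 0.02, IL6R at −1.64) and the immediate early list at 0.17 (range 0.051 to 0.33; 9 of 24 higher, 6 lower; DUSP2 at 1.31, JUN at −0.38). All of these lists lay above the central 95% of random lists. Inhibitory receptor genes had 4 of 7 higher (median 1.30), with TOX at 1.98. Their range was 0.54, with a count minimum 5 times higher, to 1.64. T-like cells were more frequent in the A.G.-ES library, and the cytotoxic gene GNLY went from 0.0578 to 0.216 UMIs per B-like cell. Free RNA from T-like cells was not tested for the inhibitory receptor and naive T lists. Cytotoxic effector genes had 10 of 12 higher (median 1.72, and 2.38 with cells thinned), led by CCL5 (2.62) and GNLY (2.60), at 198 and 419 GNLY UMIs. SRGN (0.31) and ZEB2 (−1.31) held 98.9% and 89.8% of that list's UMIs in untreated and A.G.-ES B-like cells.

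The single genes farthest apart in B-like cells were higher for SYCE3, a gene of the meiotic synaptonemal complex, at 2 and 121 UMIs (173-fold, 47.0 to 1448), RBMS3 (63.5-fold, 41.9 to 101), the potassium channel gene KCNJ3 (53.5-fold), TTN (36.8-fold) and NPAS3 (26.4-fold, from 126 and 1160 UMIs). TTN rested on few cells, with a UMI in 1.08% of A.G.-ES B-like cells against 5.36% for SYCE3. NPAS3 was also a leading gene of cluster 22, with 8 untreated and 245 A.G.-ES cells. Among the lowest were IL31RA, a cytokine receptor subunit, at 671 and 2 UMIs (ratio 0.00854, 0.00103 to 0.0310), HSPB2 at 114 and 1 (0.0251, 0.000631 to 0.143), COL8A1 at 103 and 1 (0.0278, 0.000698 to 0.158) and SNAP25 (16.7-fold lower). The median log2 ratio of all genes past the count minimum was −0.12 in B-like, −0.17 in CD4 T-like, −0.16 in SOX13-high T-like, −0.20 in CD8 T/NK-like and −0.11 in all T-like cells, and the values of single genes are to be read against it.

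In CD4 T-like cells, immediate early genes had a higher median in the A.G.-ES library, as did cytotoxic genes. Of 13 cytotoxic genes, 9 were higher and 1 lower (median 1.199, percentile 100), with GNLY at 2.86 from 36 and 857 UMIs, CTSW at 2.44, SRGN, the most counted, at 0.32 and ZEB2 at −1.53. GNLY came to 0.277 UMIs per A.G.-ES CD4 T-like cell, near the 0.216 in B-like, 0.197 in monocyte-like and 0.160 in SOX13-high T-like cells and far from the 25.9 in CD8 T/NK-like cells, so its rise is not read as expression by CD4 T-like cells. Of 22 immediate early genes, 9 were higher and 0 lower (median 0.43), with FOSB at 2.04, DUSP2 at 2.00 and JUND at 0.63. Of 15 proliferation genes, 7 were lower and 0 higher (median −0.47, percentile 1.22), but the median ranged from −0.69 with doublets kept to −0.089 with cells thinned and −0.045 with a count minimum 5 times higher, with CENPF at −2.26, MKI67 at −2.25 and HMGB2 at −0.36. Ribosomal genes had a median of 0.28 (percentile 100, range 0.27 to 0.48; RPL37A at 1.71, RPLP1 at 0.37), heat shock genes 0.12 (percentile 99.1, range 0.12 to 0.32; HSP90AA1 at 0.37, HSPA1L at 1.45) and the 4 platelet genes −1.22 (percentile 0.195; ITGB3 at −1.18, MYL9 at −1.72). Nuclear oxidative phosphorylation genes, at −0.02, stood above random lists (percentile 99.8), and their sign turned with TMM scaling, to 0.17, with centred ratios, to 0.16, without ribosomal, mitochondrial and haemoglobin genes, to 0.080, and with every cell given the same weight, to 0.045. Th1 genes (−0.05), Th2 genes (−0.29) and interferon response genes (−0.21) lay within the central 95% of random lists. The unnamed cluster nearest to platelets held 99 untreated and 25 A.G.-ES cells, and free RNA was not tested for the platelet genes.

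The 5 genes farthest up in CD4 T-like cells were RYR2, a calcium release channel gene, at 2 and 228 UMIs (34.7-fold, 9.48 to 288), ANK3 at 1 and 110 (33.4-fold, 5.88 to 1333), PRLH, which encodes prolactin-releasing hormone, at 0 and 314 (at least 31.8-fold against a floor of 3 counts), GIMAP8, a GTPase gene of lymphocytes (21.5-fold), and CFAP20DC at 3 and 212 (21.5-fold, 7.25 to 105). The 5 farthest down were THSD4 (17.7-fold lower), MCC (10.1-fold), ARHGEF26 (9.87-fold), NCAPG2, a condensin subunit gene (7.68-fold), and GRAMD1C (6.81-fold). GRAMD1C came to 0.140 UMIs per untreated CD4 T-like cell against 1.04 in B-like cells, and ANK3 to 0.0355 per A.G.-ES CD4 T-like cell against 0.174 in CD8 T/NK-like cells, and free RNA was not tested for them.

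In SOX13-high T-like cells, genes of TGF-beta signalling were lower and Treg list genes higher in the A.G.-ES library. Of 15 TGF-beta genes, 7 were lower and 0 higher (median −0.53, percentile 0.24, range −0.65 to −0.35), with the receptor gene ACVR1 at −1.31, SMAD3 at −0.92, TGFBR2 at −0.49 and SMAD4 at −0.52. Of 11 Treg list genes, 9 were higher and 2 lower (median 0.72, percentile 100, range 0.72 to 1.14): IL2RA stood at 3.17, PRDM1 at 1.85, TIGIT at 1.78, IKZF4 at 1.37, TNFRSF18 at 1.35, IKZF2 at 0.72, TNFRSF9 and RTKN2 at 0.69, ICOS at 0.60, TGFB1 at −0.71 and EBI3 at −0.80. TNFRSF9 and RTKN2 had 13 and 11 UMIs each (ratio 1.62, 0.655 to 3.91) and EBI3 20 and 6 (0.573, 0.188 to 1.48). The intervals of these genes include no change. FOXP3 had 10 and 9 UMIs in SOX13-high T-like cells. CD4 T-like cells were more frequent in the A.G.-ES library, and free RNA from them was not tested for the Treg list genes. Of 12 Th17 genes, 4 were higher, among them IL1R1 (3.60), IL17F (1.75) and RORA (1.00), and 2 were lower, IL6ST (−0.84) and IRF4 (−0.70); the median was 0.20 (percentile 99.49), and −0.011 with cells thinned, −0.030 with a count minimum 5 times higher and 0.43 with no minimum. MAF (0.45), BATF (0.41), CCR6 (−0.02), AHR (−0.04), STAT3 (−0.26) and IL6R (−0.35) lay between. NF-kB and cytokine genes had a median of 0.34 (range 0.16 to 0.52; 5 of 15 higher, 1 lower), with TNF at 3 and 29 UMIs (log2 ratio 4.21) and NFKB1 at −0.74, and interferon genes 0.19 (range 0.11 to 0.36, 4 of 26 higher, 2 lower), with IRF7 at 1.59 and EPSTI1 at 0.34. Oxidative phosphorylation (0.11, range 0.060 to 0.28, 0 of 26 past 1.5-fold) and ribosomal genes (0.09, range 0.078 to 0.27) also lay above the central 95% of random lists.

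Among single genes of these cells, PRLH was at 3 and 212 UMIs (135-fold higher, 45.5 to 659), RYR2 at 4 and 99 (47.3-fold), GIMAP8 at 7 and 160 (43.6-fold), the growth hormone receptor gene GHR at 9 and 129 (27.4-fold) and IL1R1 at 47 and 298 (12.1-fold). IL31RA was at 125 and 2 UMIs (ratio 0.0305, 0.00366 to 0.113), VIPR2, a receptor of vasoactive intestinal peptide, was 9.31-fold lower, SORCS2 7.65-fold, the B-cell transcription factor gene EBF1 7.23-fold and TNFSF11, which encodes RANKL, 6.58-fold. EBF1 came to 0.0598 UMIs per untreated SOX13-high T-like cell, near the 0.0558 in CD8 T/NK-like cells, against 16.96 in B-like cells, so its fall is not read as a change in T-like cells. GHR came to 0.114 UMIs per A.G.-ES SOX13-high T-like cell against 1.54 in CD4 T-like cells, and IL31RA to 0.0542 per untreated one against 0.196 in B-like cells. Free RNA was not tested for these 2 genes either.

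In CD8 T/NK-like cells, every measured proliferation gene was lower in the A.G.-ES library, by at least 1.5-fold in 16 of 16 (median −1.48, percentile 0), with BIRC5 at −4.70, MKI67 at −3.09 and HMGB2 at −0.74. The median was −0.65 with doublets kept, −0.70 with every cell given the same weight and −0.49 with cells thinned. Many CD8 T/NK-like medians moved as much. Cycling clusters, with 200 untreated and 33 A.G.-ES cells, were a class of their own. Their cells are left out of the proliferation values here and in the other classes. Interferon response genes were lower as well, 12 of 29 against 2 higher (median −0.55, percentile 0.17), though at −0.21 with all deposited barcodes, with MX2 at −1.91, ISG15 at −1.20 and EPSTI1 at −0.39 but RSAD2 at 1.59. Lower too were antioxidant genes (7 of 17 against 2 higher, median −0.57, but −0.29 with doublets kept, −0.33 with all deposited barcodes and −0.33 with TMM), such as GSR at −1.10 and TXN at −0.75 against FTL at 1.67, and nuclear oxidative phosphorylation genes (11 of 26 against 0, median −0.49, but −0.22 with doublets kept, −0.24 with TMM and −0.27 with all deposited barcodes), such as NDUFA8 at −1.04, while ATP5MG, the most counted, was at −0.06. Immediate early genes were higher in 13 of 21 and lower in 0 (median 0.87, range 0.43 to 1.11), with ATF3 at 1.79, FOS at 1.44 and JUN at 1.04. Cytotoxic genes differed little, with a median of 0.16 (percentile 98.4, range 0.025 to 0.41; 4 of 15 higher, 1 lower): GNLY stood at 0.16, CCL5 at 1.34 and GZMK at −1.54.

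Also in CD8 T/NK-like cells, naive and central memory genes had a median of 0.53 (5 of 15 higher, 2 lower), but 0.25 with all deposited barcodes, 0.28 with doublets kept and 0.78 with TMM, with SATB1 at 0.57 and TCF7 at 1.00, and NF-kB and cytokine genes 0.23 (range 0.081 to 0.48, 4 of 16 higher, 1 lower), with TNFAIP3 at 0.62 and IL1A at 1.58. Glucocorticoid response genes stood at 0.32 (4 of 13 higher, 1 lower), with SGK1 at 2.31 and FKBP5 at −0.25, and at −0.054 with cells thinned and 0.57 with TMM; ribosomal genes stood at 0.14 (range 0.066 to 0.39). PRLH was at 0 and 250 UMIs (at least 26.8-fold higher), C1H1orf54 at 2 and 109 (17.6-fold, 4.74 to 147; 0.0593 UMIs per A.G.-ES cell against 0.922 in B-like cells), COX3, a mitochondrial subunit of cytochrome c oxidase, 13.5-fold higher, DYNC1I1 at 0 and 113 (at least 12.1-fold) and PYGO1 at 3 and 112 (12.02-fold, 4.01 to 59.2). The lowest genes were the centromere genes CENPE (8.82-fold), CENPP (7.51-fold) and CENPF (6.84-fold), MKI67 (8.54-fold) and FABP5, a fatty acid carrier gene (6.46-fold).

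**Figure D3:**
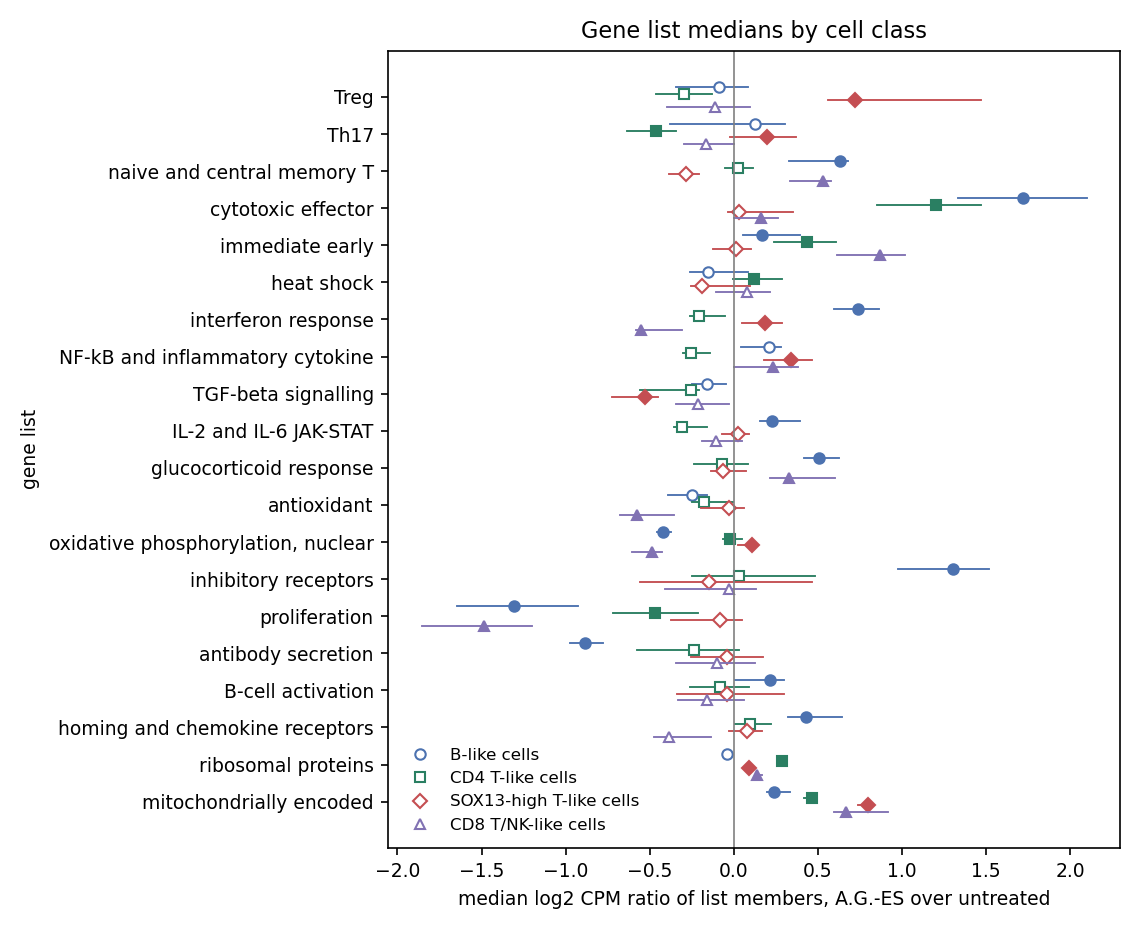
Median log2 CPM ratio of the members of each gene list, A.G.-ES over untreated (horizontal axis), in 4 cell classes, for lists with at least 5 measured members that lay outside the central 95% of random lists in some class. Filled markers lie outside that range and open ones within it, and bars are 95% intervals of counting error from Poisson resampling; proliferation stands at −1.30 in B-like and −1.48 in CD8 T/NK-like cells.

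Taken over all T-like cells, values mix the division into T-cell classes with expression per cell. Th1 genes had 5 of 12 members higher and 2 lower (median 0.51, percentile 99.98, range 0.51 to 0.82), with TNF at 1.98, IFNG at 1.62 and STAT4 at 0.31. Cytotoxic genes stood at 0.53 (7 of 15 higher, 0 lower; CCL5 at 2.22, GNLY at 1.095), but at 1.08 with all deposited barcodes and 1.09 with doublets kept. Immediate early genes stood at 0.59 (12 of 23 higher, 1 lower; DUSP2 at 1.93, JUN at 0.59), inhibitory receptors at 0.57 (4 of 9 higher, 2 lower; CTLA4 at 2.69, TOX at −0.73) and NF-kB and cytokine genes at 0.43 (range 0.17 to 0.55; 5 of 18 higher, 1 lower; IL1A at 2.14, NFKB1 at −0.77). B-cell activation (0.29, range 0.19 to 0.57; CD27 at 0.66), homing (0.28; S1PR5 at 1.52) and interferon genes (0.10, range 0.058 to 0.23; IRF7 at 1.14) also lay above the central 95% of random lists, and proliferation genes stood at −0.67 (range −0.70 to −0.36; 11 of 18 lower, 0 higher; BIRC5 at −2.77). PRLH was at 3 and 777 UMIs (157-fold higher, 53.5 to 763), CACNB4 29.9-fold higher, KCP at 0 and 126 UMIs (at least 25.5-fold), CNTN2 at 3 and 113 (22.8-fold, 7.62 to 112) and GIMAP8 22.2-fold higher. IL31RA was at 248 and 3 UMIs (ratio 0.00733, 0.00150 to 0.0217), TRPM1, a cation channel gene, at 134 and 0 (at least 73.7-fold lower), IGF2BP3 64.1-fold lower and CFAP69 33.0-fold.

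Summed over all kept cells, a whole library mixes the division into cell classes with expression per cell. The median log2 ratio of all genes was −0.08. PRLH was at 3 and 796 UMIs (341-fold higher, 116 to 1658), with a UMI in 5.91% of A.G.-ES cells, and C1R, a complement protease gene, at 15 and 1749 (150-fold). C1R, MXRA8 (36.6-fold) and CDH2 (25.6-fold), which encodes N-cadherin, were leading genes of an unnamed cluster of 46 cells, all from the A.G.-ES library. GIMAP8 was 39.7-fold higher, KCP 23.9-fold, DAPL1 22.7-fold, FLT3, a receptor of early blood progenitors and dendritic cells, 16.1-fold, FSIP1 15.2-fold and CACNB4 14.2-fold; DAPL1 led the other T-like cluster and FLT3 an unnamed cluster of 1 untreated and 27 A.G.-ES cells. IL31RA was 161.6-fold lower, from 1039 and 5 UMIs, IGF2BP3, an RNA-binding protein gene, 24.7-fold, the spectrin gene SPTB 16.5-fold, CFAP69 14.8-fold, ZNF114 12.99-fold, SORCS2 11.0-fold, the potassium channel subunit gene KCNMB3 10.7-fold, EPB41L4A 10.4-fold, NEBL 10.3-fold and RUNX1T1 10.2-fold.

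Lists of T-cell and cytotoxic genes were higher over the whole A.G.-ES library, where T-like cells were more frequent. The cytotoxic list had 13 of 15 members higher and 1 lower (median 1.56), with CCL5 at 3.06, GNLY at 2.17 and ZEB2 at −1.22. Th1 genes had 8 of 12 higher (1.12), with IFNG at 2.68 and STAT4 at 0.64, Th2 genes 3 of 6 (0.84, range 0.38 to 0.92), with CCR4 at 1.74 and GATA3 at 1.11, Treg genes 10 of 18 and 2 lower (0.70), with CTLA4 at 3.63 and TGFB1 at −0.53, and Th17 genes 6 of 14 and 1 lower (0.43), with IL23R at 4.17 and RORA at 1.28. Inhibitory receptors had 6 of 9 higher (0.92; CTLA4 at 3.63, TOX at 0.39), and IL-2 and IL-6 JAK-STAT genes 9 of 18 and 1 lower (0.58, range 0.30 to 0.66; IL2RA at 2.14, JAK1 at 0.29). Naive and central memory genes stood at 0.36 (6 of 15 higher, 1 lower; CD28 at 1.86, BACH2 at −0.15) and at −0.036 with every cell given the same weight. Homing receptors stood at 0.52 (9 of 19 higher, 2 lower; CXCR3 at 1.73, CXCR5 at −1.61).

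Inflammatory and stress lists were higher as well over the whole library, where the classes also differed. Monocyte-like cells gave 850956 of 50488226 untreated UMIs and 1879261 of 39259466 A.G.-ES UMIs. B-like cells were 45.3% of untreated and 22.2% of A.G.-ES cells. The values below do not separate these shifts from expression per cell. NF-kB and cytokine genes stood at 0.82 (11 of 20 higher, 1 lower; TNF at 2.26, NFKB1 at −0.53), and at 0.054 with every cell given the same weight, interferon genes at 0.71 (range 0.41 to 0.80; 17 of 30 higher, 1 lower; IRF7 at 1.88, EPSTI1 at −0.15) and glucocorticoid genes at 0.60 (range 0.34 to 0.68; 8 of 15 higher, 1 lower; SGK1 at 1.75, FKBP5 at 0.62). Immediate early genes stood at 0.56 (12 of 25 higher, 4 lower; CD69 at 1.56, MYC at −1.67) and heat shock genes at 0.26 (5 of 15 higher, 2 lower; HSPB1 at 1.65, HSP90AB1 at −0.50). Phagocytosis genes stood at 1.05 (9 of 14 higher, 3 lower; MSR1 at 2.40, MRC1 at −2.73), and at 0.36 with cells thinned, and neutrophil genes at 1.44 (5 of 6 higher, 1 lower; BPI at 2.39, CXCL8 at 1.11), and at 0.54 with cells thinned. Proliferation genes were lower in 15 of 19 and higher in 0 (−1.51; UBE2C at −2.44, HMGB2 at −0.45), antibody secretion genes in 6 of 10 and higher in 2 (−1.25, range −1.28 to −0.69; JCHAIN at −2.58, PRDM1 at 1.31), and nuclear oxidative phosphorylation genes in 2 of 26 and higher in 0 (−0.34; SDHB at −0.88). All of these lists lay outside the central 95% of random lists. Within that range were MHC class II genes (3 measured, −0.49), TGF-beta signalling (−0.02), antioxidant (0.05), apoptosis and p53 (−0.08), B-cell activation (−0.13), platelet (−0.59), erythroid (1 gene, CA2, 1.17) and ribosomal genes (−0.10).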

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

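Clustering on the marker genes alone, leaving Y-chromosome and mitochondrial genes out of the variable genes, and comparing monocyte-like cells were alternatives chosen after seeing the data, and the others before. No paired analysis was possible because each group holds 1 library. Depth limits the Treg and Th17 genes, such as FOXP3 with 76 and 100 UMIs and IL23R with 1 and 22 UMIs in CD4 T-like cells.

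The share differences of B-like, CD4 T-like, SOX13-high T-like and CD8 T/NK-like cells each kept their direction over 10 alternatives. Those of the other classes and of all T-like cells were not taken through the alternatives. In points, A.G.-ES minus untreated, the B-like difference of −23.1 became −25.0 with doublets kept, −24.6 with each library clustered on its own and −19.6 with 4000 genes and 50 components. The CD4 T-like difference of 24.3 became 27.7 on markers alone. The SOX13-high difference of −17.5 became −16.0 with all deposited barcodes and −14.6 with each library clustered on its own. The CD8 T/NK-like difference of 15.4 became 16.4 with all deposited barcodes, 16.4 with doublets kept, 16.6 at Scrublet's own threshold and 12.8 on markers alone. The cause was not tested.

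No named gene reversed, and 607 of 699 values of named genes under alternatives stayed within their counting interval. Which genes were named depended on the count minimum and on thinning. Of the 20 genes named over the whole library, 7 were still named with cells thinned, 4 with no minimum and 7 with a minimum 5 times higher. Of 10 named genes each, the numbers in that order were 4, 6 and 4 in B-like cells, 4, 4 and 0 in CD4 T-like cells, 2, 3 and 2 in SOX13-high T-like cells and 1, 2 and 1 in CD8 T/NK-like cells. On markers alone 5 were still named in CD4 T-like, 6 in SOX13-high and 4 in CD8 T/NK-like cells. In CD8 T/NK-like cells 6 were still named with all deposited barcodes, 5 with doublets kept, 4 at resolution 2, 4 with Y-chromosome and mitochondrial genes left out and 5 with every cell given the same weight, where the cause was not tested.

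Of the Treg and Th17 values in T-like cells, 52 of 60 stayed within their intervals. Over all T-like cells the Treg median of 0.21 became 0.60 with cells thinned and the Th17 median of −0.08 became 0.22, with the sign turned, with every cell given the same weight. In CD4 T-like cells the Treg median of −0.30 became −0.10 with TMM, −0.11 with centred ratios, −0.075 with every cell given the same weight and −0.49 with cells thinned, and the Th17 median of −0.46 became −0.27 with TMM and −0.28 with centred ratios. The difference in the CD4 T-like share with a FOXP3 UMI, −2.32 points, became −0.842 at 1000 UMIs. The causes were not tested.

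The next counts leave out the Treg and Th17 lists in all T-like and CD4 T-like cells. Of 70 other list medians past the range of random lists, 60 to 70 kept their sign under each alternative, and 60 without ribosomal, mitochondrial and haemoglobin genes, where the lists of those genes give no value. The sign turned for nuclear oxidative phosphorylation in CD4 T-like cells, from −0.02 to 0.17 with TMM, 0.080 without those genes, 0.16 with centred ratios and 0.045 with every cell given the same weight. It also turned for naive and central memory genes over the whole library (−0.036 with every cell given the same weight), for Th17 genes in SOX13-high T-like cells (−0.011 with cells thinned, −0.030 with a minimum 5 times higher) and for glucocorticoid genes in CD8 T/NK-like cells (−0.054 with cells thinned). The cause was not tested.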

Other observations

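Of the tests in this part, those of different sexes, of dilution by other CD4 T-like cells, of depth, and of free RNA, and the doublet test on the shorter list, were chosen after the result was seen; those of mixed sexes, of clusters and of doublets on the whole list were set before. The comparison of monocyte-like cells and the choice of 6 Y-linked genes were also made after seeing the data.

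Monocyte-like cells were compared although the untreated library held 179 of them against 290. C1QB, a chain of complement C1q, was at 0 and 106 UMIs (at least 16.0-fold higher in A.G.-ES), in 2.41% of A.G.-ES monocyte-like cells, and CXCL10, an interferon-induced chemokine gene, at 4 and 119 (13.5-fold, 5.13 to 50.3). COX3 was 11.8-fold higher, CRYL1 7.17-fold and POLK 6.00-fold. SYNE2 was 10.1-fold lower, ATP11A 4.87-fold, ITGA9 4.58-fold, CHD7 4.48-fold and APBA1 3.97-fold. These cells had a median of 4127 UMIs in the untreated and 6405.5 in the A.G.-ES library.

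Mitochondrially encoded genes had higher medians in the A.G.-ES library, at 0.24 in B-like (0.20 to 0.37 over the alternatives), 0.46 in CD4 T-like, 0.67 in CD8 T/NK-like, 0.80 in SOX13-high T-like and 0.76 in all T-like cells and 0.55 over the whole library. Of 13 members, those at least 1.5-fold higher and lower numbered 3 and 1 in B-like, 4 and 1 in CD4 T-like, 9 and 0 in CD8 T/NK-like, 8 and 0 in SOX13-high T-like and 6 and 1 over the whole library. Nuclear genes of oxidative phosphorylation had medians of −0.42 in B-like, −0.02 in CD4 T-like, −0.49 in CD8 T/NK-like and 0.11 in SOX13-high T-like cells. The share of UMIs from mitochondrially encoded genes went from 1.33% to 1.74% in B-like, 1.45% to 2.25% in CD4 T-like, 1.12% to 2.04% in SOX13-high T-like and 1.43% to 2.57% in CD8 T/NK-like cells. The members moved unequally: over the whole library COX3 stood at 3.60 on the log2 scale, from 9315 and 87822 UMIs, ND1 at 1.88 and ND4L at −0.73. COX3 stood at 3.36 in B-like, 3.45 in CD4 T-like, 3.45 in SOX13-high T-like and 3.75 in CD8 T/NK-like cells.

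The 6 most counted Y-linked genes were present in the untreated library and nearly absent from the A.G.-ES library: LOC132659058, LOC132659055, LOC132659061, LOC132659062, LOC132659059 and LOC132659056 together were at 768 CPM (760 to 775) against 0.229 CPM (0.105 to 0.435). Of the less counted Y-linked genes, LOC132657159 at 86 and 5 UMIs (ratio 0.0748, 0.0237 to 0.181) and LOC132658880 at 40 and 0 went the same way, while LOC106990378 was at 248 and 190 UMIs (ratio 0.985), LOC132659048 at 73 and 32 (0.564) and LOC105611500 at 33 and 17 (0.662) differed far less. All 85 Y-linked genes together had 40414 and 755 UMIs, 475 of the latter from LOC132657141. The untreated library lacked a Y UMI in 10.8% of cells where depth alone gives 7.31%, an excess of 3.46 points, which argues against a large share of female cells in it and leaves a small share open. Over the Y genes with at least 1000 untreated UMIs, the A.G.-ES level was 1.56% of the untreated one, and 0.0299% without LOC132657141. Male animals behind the untreated and female ones behind the A.G.-ES library are a candidate explanation. LOC132657141, at 1132 and 475 UMIs, did not meet the bound, which was set for each Y gene with at least 1000 untreated UMIs. By that rule the explanation stays open. LOC106990378, LOC132659048 and LOC105611500, too little counted for the bound, also differed far less. Why these genes remained was not tested. The 6 most counted genes met the bound, at no more than 0.124% of the untreated level in any class compared. A UMI of these 6 genes was found in 89.2% of untreated and 0.103% of A.G.-ES cells, so cells with them were nearly absent from the A.G.-ES library. Sex, the animals themselves and the treatment cannot be told apart in any difference between these libraries.

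FOXP3 was lower per UMI in the CD4 T-like cells of the A.G.-ES library. Fewer UMIs per cell are argued against, since the share of thinned cells with a FOXP3 UMI was still 3.07 times higher in the untreated library. Of all kept cells, 0.385% in the untreated and 0.408% in the A.G.-ES library were CD4 T-like with a FOXP3 UMI after thinning (27 and 33 cells). The ratio was 1.06, within the 1.5-fold limits set, but its interval (0.618 to 1.83) reaches past them both ways. The lower level may come from more CD4 T-like cells without FOXP3 beside as many with it, and this stays open. The share is taken of all kept cells, whose division into classes also differed. Different clusters in the libraries stay open: in cluster 11, the most evenly split, the FOXP3 ratio was 0.416 (0.204 to 0.793) from 40 and 13 UMIs, and its interval reaches past the bound set, which was 1 divided by 1.5. Cluster 11 held 541 untreated and 442 A.G.-ES cells, so FOXP3 was lower there although the cluster was not larger in the A.G.-ES library. No biological explanation beyond the treatment, which is confounded with the library, was tested.

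Cytotoxic genes had a higher median in the B-like cells of the A.G.-ES library, but SRGN and ZEB2, which B-like cells carry themselves, made up most of the list's UMIs there. Over the whole list GNLY's share of UMIs was 9.28 times higher in CD8 T/NK-like than in B-like cells (51.2% against 5.52%). This is past the bound written against free RNA, but SRGN and ZEB2 held 89.8% of the list's UMIs in these B-like cells, which fixes a low GNLY share beforehand, so it decides nothing. Without SRGN and ZEB2 the shares were 55.7% and 54.1%, a ratio of 1.03, and 35.8% in monocyte-like cells, with 0.399, 0.548 and 46.6 UMIs per B-like, monocyte-like and CD8 T/NK-like cell, so free RNA from CD8 T/NK-like cells may account for the other members. The 1% of B-like cells with most list UMIs held 9.62% of them; this lies under the bound of 10% written against doublets, but the bound was wrong for a list ruled by 2 genes of B-like cells, and without them the share was 17.7%. Doublets therefore stay open as a part of the pattern, and a change in B-like cells themselves was not tested apart from the treatment. In CD4 T-like cells of the A.G.-ES library GNLY came to 0.277 UMIs per cell, against 0.216 in B-like and 0.197 in monocyte-like cells, and free RNA was not tested for that class.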
